A study of Homo sapiens with 15 samples.

How the data were processed

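Gene expression was measured on 15 Affymetrix arrays hybridised with RNA of HEK293T cells, a human embryonic kidney cell line that takes up and expresses foreign DNA readily. The labels give 6 arrays of control cells that were never exposed to transfection, 6 arrays of cells labelled transfected and 3 arrays of cells labelled untransfected, the last 2 groups at 24 h. The labels attach GFP to the transfected and GFPMINUS to the untransfected arrays; how the cells were separated is not given in the sources used here. Per the labels' protocols, total RNA was extracted with Trizol, and biotinylated cRNA was made from 15 ug of it in a reaction at 37C for 16h. The labels call the replicates biological, and whether they came from separate cultures is not given in the sources used here, so p-values measure only the spread between these samples, which may be technical.

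The deposited value table holds log2 values for 54675 probe sets, which the authors computed by robust multi-array averaging (RMA) in R 2.9.0, per the submitters' processing notes. RMA in general subtracts background, normalizes the arrays against each other and summarises the probes of a probe set, and it compresses differences of dim probe sets. The columns' medians lay between 5.05 and 5.14, but their SDs ranged from 2.10 to 2.47, so the 15 columns do not share one distribution. The scale is log2, while the way the arrays were grouped during normalization stays unknown. The authors also deposited limma tables of the 3 comparisons, which hold a log2 change, a moderated t score and a p-value with its adjusted form for each probe set, per the file headers. For the 3 comparisons, the log2 changes in the authors' deposited tables differed from those computed here by at most 4.98e-08. Scanner files were not used here, so no detection call is given for any probe set, and the number of arrays limits the precision.

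The 62 Affymetrix control probe sets were left out of the tests, which leaves 54613 probe sets. The gene table assigned 1 symbol to 41091 of them and several to 1801, while 11721 had no symbol in that table and are unnamed here. Of the single-symbol probe sets, 41037 had their symbol updated or kept through Entrez numbers with the RefSeq gene table of assembly GRCh38.p14, used for names only. A gene is represented by its brightest probe set among those with that single symbol, which gives 19775 genes. No 2 arrays held identical values.

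Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 15 arrays, with group as the only factor, two-sided, and Benjamini-Hochberg adjustment over the 54613 probe sets; a probe set was called at an adjusted p under 0.05. The submitters name limma too. Before the data were examined, 29 gene lists with 692 entries were fixed, of which 65 entries had no single-symbol probe set. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 29 lists within a comparison. The last 4 lists check for leukocyte, fibroblast and neuronal markers and for scaling (reference genes). RNA quality was read from the control probe sets at the 3-prime and 5-prime ends of GAPDH and ACTB, with exact permutation tests between groups.

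The naming rule was fixed at the same time. In each comparison it takes up to 12 genes with the largest rise and up to 12 with the largest fall among genes with an adjusted p under 0.05 whose values do not overlap between the 2 groups, and up to 4 called members of each list that is called or described. Where no member passes, it takes at most 2 members, given as values, and where no gene passes, 5 genes in each direction with the smallest p, as values that do not pass. Genes named from the fit with the deposit set as a block follow the same rule applied to that fit, with non-overlap asked within each set that holds both groups; this use of the rule, and any probe set outside it, was chosen after the values were seen.

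The arrays were deposited in 2 runs of sample numbers, called deposit sets here: set 1 holds replicates 1 to 3 of control and transfected cells, and set 2 holds replicates 4 to 6 of both and all untransfected arrays. Arrays correlated at 0.989 on average within their own set and at 0.976 with the other set (means over the 15 arrays), and transfected and control cells are balanced over the sets, while untransfected cells lie in set 2 alone. The set was therefore fitted as a block beside group, an alternative fixed together with the lists. Control and transfected arrays share replicate numbers 1 to 6. The deviations of same-numbered control and transfected arrays from their group means correlated at 0.498 to 0.829 in all 6 pairs, above the limit of 0.1 set for pairing. With the set means removed as well, these correlations were -0.039 to 0.056 in set 1 and 0.484 to 0.69 in set 2. With so few arrays per group, 1 number that stands apart in both groups can make every correlation in set 2 positive. Array 5 had the lowest mean correlation with its group in set 2, both among controls (0.991) and among transfected arrays (0.967). Pairing by number beyond the set is thus not shown. Untransfected arrays correlated at -0.15 to 0.09 with the control arrays and at -0.17 to 0.05 with the transfected arrays of the same number, which lie in the other set.

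Other alternatives were a fit on the 2 groups alone, filters on dim probe sets (a value above 5 on at least 3 arrays, or mean values above the median), quantile normalization, median centring, an intensity trend with robust hyperparameters, array weights, other thresholds, 1 value per gene, each set alone, leaving out each array, camera with an estimated correlation and fry. Combinations with the deposit set, fits without transfected array 5 the replicate block within each set and list tests within each set were added after the data were seen. The functions were tested on simulated data with 200 changed probe sets among 54613 and the real set effect. For transfected against control, 68.7% of planted log2 changes of 1 were recovered without the block and 95.5% with it; for untransfected against control the shares were 50.7% and 70.1%, and for transfected against untransfected, with 400 changed probe sets, 62.7% and 82.8%. In the same order, false calls without and with the block were 2 and 11, 3 and 6, and 4 and 14. The simulated noise was independent, with the same SD on every array for a probe set. The real arrays had weights from 0.304 to 2.44, so these shares may be too high for them.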

Results

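The series profiled HEK293T cells by microarray to follow which cellular pathways respond to nonviral gene delivery, that is, to genetic material brought in without a virus. There were 6 arrays of control cells, 6 of transfected cells and 3 of untransfected cells, the last 2 groups collected at 24 h. All levels are log2 RMA values, on which array medians lay near 5.08, and a log2 change of 1 is a doubling on that scale. The arrays fell into 2 deposit sets that differed at 20443 of the 54613 probe sets, or 37.4%, in a limma fit on control and transfected arrays. Values with the set as a block are therefore given beside the unblocked ones.

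Transfected cells were compared with control cells to find the genes that differ in cells that received and expressed the DNA. HSPA6, an inducible member of the HSP70 chaperone family, rose by 3.59 on the log2 scale (95% interval 3.23 to 3.94), from 4.93 ± 0.29 (SD, n = 6) in control to 8.52 ± 0.36 (SD, n = 6) in transfected cells. Its control level lies near the array medians, and RMA compresses differences of dim probe sets, so the size is approximate. ATF3, a transcription factor induced by stress, rose 3.78-fold (2.98 to 4.78), and HMOX1, the heme-degrading heme oxygenase 1, rose 3.18-fold (2.11 to 4.80). DDB2, a DNA damage recognition protein and p53 target, rose 2.52-fold (2.00 to 3.17). Fewer genes were lower: BTN3A2, a butyrophilin, fell by 0.97 on the log2 scale, and AMOT, the angiomotin scaffold protein, fell by 0.92.

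The 2 largest rises were at probe sets annotated to RAP1A, a small GTPase of the RAS family, which were singled out after their values were seen. The first went from 4.84 ± 0.38 (SD, n = 6) in control to 13.92 ± 0.21 (SD, n = 6) in transfected cells, a log2 change of 9.08 (SE 0.16, limma adjusted p = 5.56e-14). The second, whose suffix marks probes that also match other sequences, rose by 9.99 (SE 0.27, limma adjusted p = 1.12e-11). Transfected arrays had values of 13.64 to 14.56 at both, close to the highest value of any probe set on these arrays, 14.25 to 14.95. Control values at both lay near or below the array medians, so the changes may be compressed at either end and their sizes are approximate. The other RAP1A probe sets did not pass: the brightest, and so the gene's representative, had a log2 change of -0.05 (95% interval -0.72 to 0.63, limma adjusted p = 0.999), and the last one of -0.35 (-0.68 to -0.02, limma adjusted p = 0.624). A probe set without a symbol here rose by 2.99 (SE 0.22, limma adjusted p = 6.97e-06).

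**Figure D1:**
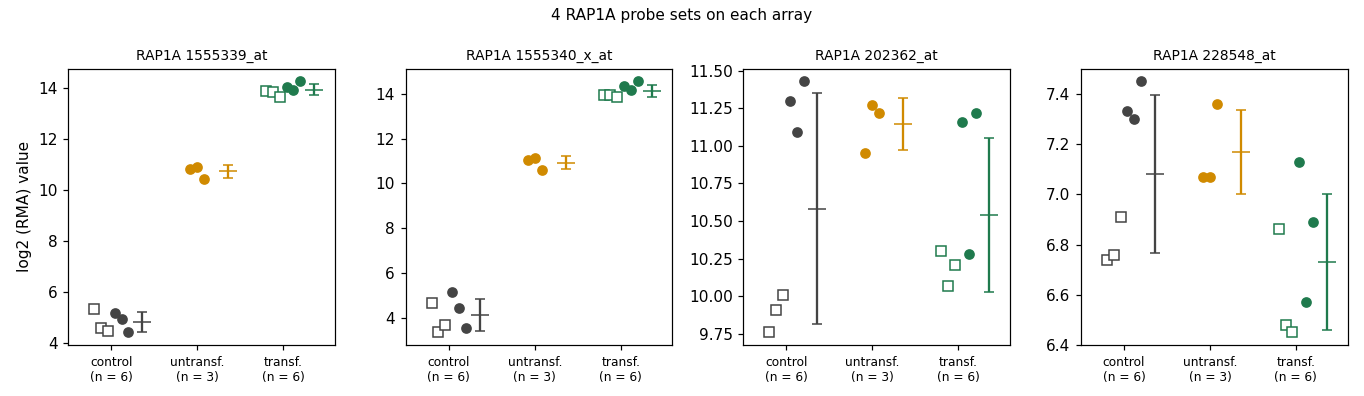
log2 (RMA) value (y axis, scaled separately in each panel) of the 4 RAP1A probe sets on every array by group (x axis); open squares are deposit set 1, filled circles set 2, and crosses with bars the mean ± SD. In the 2 panels of the probe sets that rose, the untransfected arrays lie between control and transfected arrays, with untransfected means of 10.72 and 10.92; the other RAP1A probe sets had log2 changes of -0.05 and -0.35 in transfected cells.

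In all, limma called 72 of 54613 probe sets, 67 higher and 5 lower, which included the representatives of 32 higher and 4 lower genes. With quantile normalization the split was 97 higher and 47 lower. The genes with the next largest rises were GDF15, a secreted stress cytokine, by 1.37 (SE 0.21, limma adjusted p = 0.0168), SLC1A4, a neutral amino acid transporter, by 1.35 (SE 0.24, adjusted p = 0.0367), and POMZP3 by 1.34 (SE 0.16, adjusted p = 0.00141). They were followed by ZNF79 (1.18), the HSP40 cochaperone DNAJB1 (1.14), SLC3A2, the heavy chain of amino acid transporters (1.09), smooth muscle actin ACTA2 (1.08) and ZNF473 (1.00), with limma adjusted p from 3.87e-06 to 0.0318. LAMA1, a laminin chain, and SLC9A3-AS1 fell by 0.60 and 0.53. The size depended on the probe set for some genes: as the mean of all probe sets of the gene the log2 change was 2.75 for HSPA6, whose other probe set rose by 1.92, and 1.26 for ATF3, and the calls of GDF15 (0.57, limma adjusted p = 0.101), ACTA2 (0.36, adjusted p = 0.0911) and LAMA1 (-0.21, adjusted p = 0.351) ended.

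The unblocked calls of 8 genes named in this comparison, members of the fixed lists among them, ended in limma when certain single arrays were left out (adjusted p of at most 0.128), though all 8 passed with the set as a block. HMOX1 was lost without control 1, 2 or 3 or transfected 2, 4 or 6, GDF15 without control 1 or 2 or transfected 6, and PPP1R15A without control 1 or 6 or transfected 2. SLC1A4, ACTA2, BTN3A2 and LAMA1 were lost in 9 of 12 such fits and HYOU1 in 8. SLC1A4 passed without transfected 1, 3 or 5, ACTA2 without transfected 3, 4 or 5, BTN3A2 without control 3 or transfected 4 or 5, LAMA1 without control 2 or 3 or transfected 4, and HYOU1 without control 2 or transfected 2, 4 or 5.

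**Figure D2:**
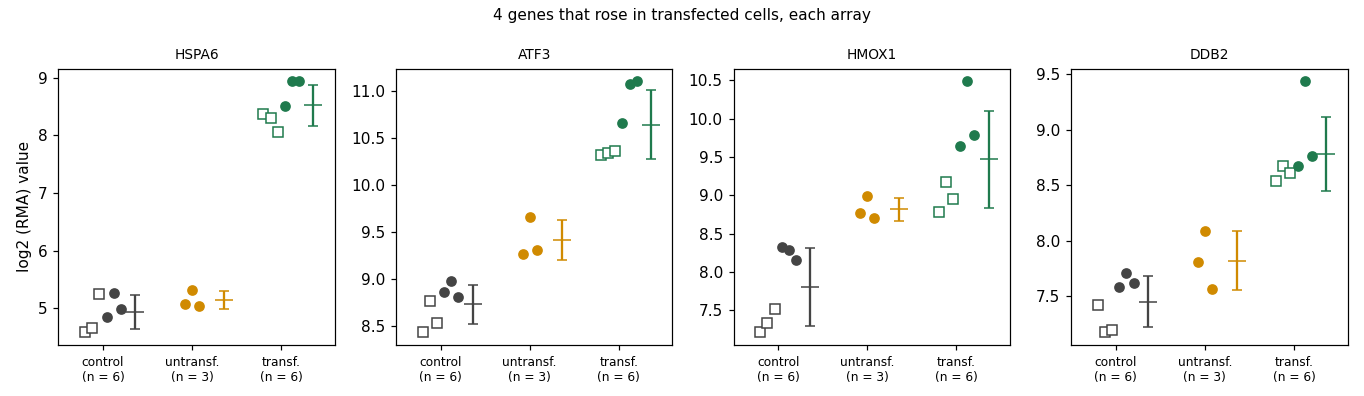
log2 (RMA) value (y axis, scaled separately in each panel) of HSPA6, ATF3, HMOX1 and DDB2 on every array by group (x axis); open squares are deposit set 1, filled circles set 2, and crosses with bars the mean ± SD. Every transfected array lies above every control array, as the naming rule asks, and HSPA6 stood at 5.15 in untransfected cells against 4.93 in control.

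Among the fixed lists, the integrated stress response, the program that ATF4 drives when translation is restrained, had all 25 measured genes above 0, with a mean log2 change of 0.68; 3 rose, namely ATF3, SLC3A2 and PPP1R15A, which encodes the GADD34 phosphatase subunit (1.00, limma adjusted p = 0.0171), and adjusted over the list alone 15 rose. Of 19 genes for heat shock and chaperones 2 rose (HSPA6 and DNAJB1) and adjusted over the list alone 5 did, with a mean of 0.59, a median of 0.37 and a mean of 0.42 without HSPA6. All 21 p53 targets were above 0 with a mean of 0.56, and 17 of them were in set 2 alone. Of these targets 1, DDB2, rose, and adjusted over the list alone 9 did. The activity of p53 itself was not measured, so whether p53 drove any of these rises is not known. Camera's adjusted p was 3.49e-18, 1.17e-08 and 7.08e-12 for these lists. It was 0.303 for each with an estimated correlation, and 0.00382, 0.0116 and 0.00155 with an estimated correlation and the set as a block. In set 1 and set 2 alone the means were 0.70 and 0.66 for the integrated stress response, 0.74 and 0.43 for heat shock and 0.68 and 0.44 for p53 targets, with camera adjusted p of at most 0.000506, and from 0.0671 to 0.156 with an estimated correlation. Reference genes had a mean of 0.47 in set 1, where they were called upward (camera adjusted p = 8.5e-07, and 0.368 with an estimated correlation). In set 2 their mean was 0.001, with a downward test that was not called.

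Camera called 10 of 29 lists, 9 upward and 1 downward. The other upward calls were endoplasmic reticulum chaperones (mean 0.27; HYOU1 rose by 0.49), DNA replication (0.28), histones (0.26), oxidative stress and NRF2 targets (0.28; HMOX1 rose), lysosome and autophagy (0.21), and endocytosis and trafficking (0.19), with adjusted p from 0.000119 to 0.0345. Adjusted over the list alone 1, 5, 0, 2, 2 and 0 of their members rose. No member of the replication, histone, lysosome or endocytosis lists rose on its own in limma, and the largest values were 0.77 for MCM5 and 0.57 for E2F1 in replication, 0.70 for SQSTM1 in lysosome, and 0.56 for CLTB in endocytosis. Extracellular matrix and adhesion genes were called downward (mean -0.12, adjusted p = 0.00576), where LAMA1 fell; adjusted over the list alone 1 member rose and 1 fell. The endocytosis call was lost after quantile normalization (adjusted p = 0.195). With an estimated correlation each of these 7 lists had an adjusted p = 0.811. None of the 7 was called within both sets: histones (means of 0.22 in set 1 and 0.29 in set 2) and extracellular matrix (0.01, with a downward test, and -0.26) were called in set 2, and endoplasmic reticulum chaperones (0.42 and 0.115), replication (0.43 and 0.13), NRF2 targets (0.36 and 0.20), lysosome (0.31 and 0.11) and endocytosis (0.36 and 0.02, the latter with a median of -0.014) in set 1. With an estimated correlation none of these calls within a set held (camera adjusted p from 0.0671 to 0.411). Reference genes, the check for scaling, had a mean of 0.47 in set 1, above all of the lists just named, and 0.23 over both sets. A shift of scale is thus not excluded for these lists. G2 and mitosis genes, not called over both sets, had 0.22 in set 1 and -0.26 in set 2 (camera adjusted p = 0.00708 and 1.86e-05, and 0.582 and 0.0671 with an estimated correlation), a difference that was not tested. The 37 interferon-stimulated genes, a usual readout of sensed foreign nucleic acid, were not called (mean -0.02, median 0.01, adjusted p = 0.2), nor were the 25 genes of nucleic acid sensing (mean 0.08, adjusted p = 0.536). Adjusted over the list alone no member of either passed. Whether these cells can raise such genes was not tested, so the missing call does not show that the DNA went unsensed. In set 1 alone the interferon-stimulated genes were called downward (mean -0.01, camera adjusted p = 0.0342, and 0.209 with an estimated correlation). In set 2 alone they were not (mean -0.02, camera adjusted p = 0.739).

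With the deposit set as a block, limma called 859 probe sets, 722 higher and 137 lower, including all 72 above, and 456 genes. Each of these genes had the same direction in both sets. Passing a fit over both sets nearly requires this, so it is no independent check. By the same rule this fit added CHAC1 (1.32, limma adjusted p = 0.000209), CTH (1.24; 9.17e-06) and SESN2 (1.14; 0.00018), members of the integrated stress response list with 15 of 25 genes now higher. It added BAG3 (0.95) and SERPINH1 (0.68) to the heat shock list, with 6 of 19 higher. Among p53 targets it added GADD45A (1.03), TP53I3 (0.92) and the cell cycle inhibitor CDKN1A (0.92), with 10 of 21 higher. MCM5, E2F1, MCM7 and MCM2 were among 8 of 29 replication genes that rose in it, and SQSTM1, GCLM and FTL joined HMOX1 in the oxidative stress list. With the replicate number as a block the count was 1463.

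For transfected versus control within replicates 1 to 3 limma called 3770 probe sets and within replicates 4 to 6 it called 4, or 6 with the replicate number as a block; transfected array 5 stood apart in the second set, and with the set as a block but without that array the count was 2049. In the first set the difference between 3-prime and 5-prime signal of ACTB, a sign of RNA quality, was 0.74 ± 0.10 in transfected and 1.37 ± 0.29 in control cells (SD, n = 3, exact permutation p = 0.1, two-sided and the smallest that 3 against 3 arrays can give), with no overlap. In the second set it was 1.03 ± 0.14 and 1.05 ± 0.07 (SD, n = 3, exact permutation p = 0.9). For GAPDH it was 0.16 and 0.35 in the first set and 0.28 and 0.19 in the second (exact permutation p = 0.1 and 0.2). The unblocked count fell to 34 without control array 1, 38 without transfected array 2, 39 without transfected array 6, 43 without control array 2 and 44 without control array 6.

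Untransfected cells were compared with control cells to see what cells show that went through the procedure but were classed as not expressing the DNA. The same 2 RAP1A probe sets rose here too, by 5.89 (SE 0.20, limma adjusted p = 6.94e-10) and 6.78 (SE 0.33, limma adjusted p = 6.4e-08), to 10.72 ± 0.25 and 10.92 ± 0.29 (SD, n = 3). A pair of probe sets without symbols here, the first of which rose in transfected cells too, rose by 2.24 and 1.23 (limma adjusted p = 0.00729 and 0.00534). These 4 were the only calls, none of them a gene's representative, and they are named because the count is so small. Limma gave 2777 probe sets at an unadjusted p under 0.05, and 1554 with the set as a block, where chance gives 2731. Neither count shows that nothing changed: the unblocked spread takes in the set, and the blocked count lies under chance. With the set as a block the same 4 were called, and leaving out any 1 untransfected array left 2, the RAP1A probe sets.

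No gene passed. The genes with the smallest p and a positive value were HYOU1, an endoplasmic reticulum chaperone (0.57), SLC3A2 (0.67), PAPOLA-DT (0.53), the histone gene H2AC17 (1.25) and NEU1, a lysosomal sialidase (0.60). Those with a negative value were KIF21B (-0.53), BASP1 (-0.63), STAT4 (-0.41), C14orf132 (-0.57) and NHSL2 (-0.37). Limma's adjusted p was 0.461 for HYOU1 and 0.649 for the others.

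Untransfected arrays lie in set 2 alone, so the lists are given with the set as a block: without the block camera called 22 of 29 lists, reference genes among them (mean 0.56), and with the block 13. None of the 22 held with an estimated correlation (lowest adjusted p = 0.451). With the block, the 19 endoplasmic reticulum chaperone genes were all above 0 with a mean of 0.32, and 23 of the 25 integrated stress response genes were, with a mean of 0.28; camera's adjusted p was 5.07e-14 for both, and 0.0329 and 0.0364 with an estimated correlation. None of these genes rose alone, but adjusted over the list alone 1 and 5 did; HSP90B1 had a value of 0.78 and SLC7A11 one of 0.70, and within set 2, against controls 4 to 6, they had 0.49 and 0.69 (limma adjusted p = 0.98 for both). Within set 2 the means of these 2 lists were 0.24 and 0.27, with camera adjusted p of 9.14e-12 and 1.93e-12, but 0.151 and 0.528 with an estimated correlation. Without transfected array 5, which helps to set the size of the block, the adjusted p with an estimated correlation was 0.0954 for both. The p53 targets (mean 0.15, adjusted p = 0.00305, and 0.23 with an estimated correlation) and G2 and mitosis genes (mean 0.21, adjusted p = 4.44e-05, and 0.36 with an estimated correlation) were called upward, and interferon-stimulated genes downward (mean -0.10, adjusted p = 0.00235, and 0.36 with an estimated correlation). Heat shock and chaperone genes were not called (mean 0.08, adjusted p = 0.218). Within set 2 these 4 lists had means of 0.09, 0.09, -0.10 and 0.01 (adjusted p = 0.0466, 0.133, 0.0299 and 0.699, and 0.528 or more with an estimated correlation), so the G2 and mitosis call ended. Adjusted over the list alone no member of these last 4 lists passed.

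Transfected and untransfected cells were then set against each other, both at 24 h. HSPA6 was 10.3-fold higher in transfected cells (95% interval 7.64 to 14.0, limma adjusted p = 2.41e-06), at 8.52 ± 0.36 (SD, n = 6) against 5.15 ± 0.15 (SD, n = 3). The untransfected level lies near the array medians of 5.08. RMA compresses differences of dim probe sets, so this fold is approximate. The 2 RAP1A probe sets were higher by 3.20 (SE 0.20, limma adjusted p = 2.41e-06) and 3.21 (SE 0.33, limma adjusted p = 0.00107). Their transfected values lie near the arrays' highest, where a saturated signal would make these differences too small. The zinc finger genes ZNF79 and ZNF473 rose by 0.90 (SE 0.10, limma adjusted p = 0.00237) and 0.89 (SE 0.13, limma adjusted p = 0.0421). Limma called 8 probe sets, all higher, and 3309 at an unadjusted p under 0.05. Leaving out any 1 array of either group gave 5 or 6, and ZNF473 did not pass when any 1 of them was left out. As the mean of all probe sets of the gene, HSPA6 was higher by 2.47 on the log2 scale, with 1.57 at its other probe set, and ZNF79 did not pass (0.65, limma adjusted p = 0.0542).

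With the set as a block limma called 25 probe sets, 24 higher and 1 lower. By the same rule the added genes were ATF3 (1.46), DDB2 (1.15), HMOX1 (1.13), DNAJB1 (1.06), LPXN, a focal adhesion protein (1.01), BAG3, an HSP70 cochaperone (0.97), POMZP3 (0.83), LOC374443 (0.80) and SNHG32 (0.75), with limma adjusted p from 0.000191 to 0.0423. BTN3A2 fell by 0.64 (limma adjusted p = 0.0262). Without the block ATF3 had a value of 1.24 (limma adjusted p = 0.0823) and none of these genes passed.

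Camera called 13 lists without the block, 2 upward and 11 downward, and 10 with it, 6 upward and 4 downward. None of the 13 held with an estimated correlation (lowest adjusted p = 0.699). With the block, heat shock and chaperones (mean 0.50, median 0.20), integrated stress response (mean 0.40, median 0.35) and p53 targets (mean 0.41, median 0.39) were called upward, with adjusted p of 2.87e-09, 1.24e-13 and 3.24e-11, and 0.0206, 0.0265 and 0.00499 with an estimated correlation. Without HSPA6 the heat shock mean was 0.33, and without the block the median of that list was 0.002. Within set 2 the 3 means were 0.425, 0.395 and 0.355 (adjusted p of at most 6.76e-05, and 0.0878, 0.16 and 0.0878 with an estimated correlation). In these lists 3, 1 and 1 genes rose, and adjusted over the list alone 5, 11 and 11 did. DNA replication genes were called upward (mean 0.29, adjusted p = 3.24e-11, and 0.0974 with an estimated correlation) and G2 and mitosis genes downward (mean -0.23, adjusted p = 4.03e-07, and 0.273 with an estimated correlation), with no member passing in either; adjusted over the list alone 12 replication genes rose. Within set 2 these had means of 0.21 and -0.35 (adjusted p = 2.84e-05 and 9.23e-11, and 0.106 and 0.0399 with an estimated correlation). Without transfected array 5 the integrated stress response had an adjusted p = 0.056 with an estimated correlation. Endoplasmic reticulum chaperones, called downward without the block (mean -0.36, adjusted p = 0.00025), were not called with it (mean -0.05, adjusted p = 0.176), but were within set 2 (mean -0.125, adjusted p = 0.0327, and 0.177 with an estimated correlation).

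**Figure D3:**
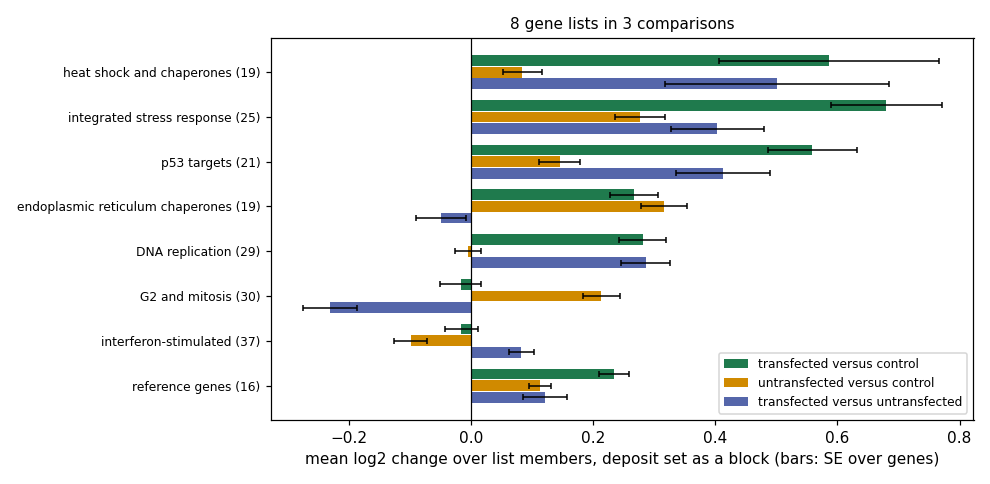
Mean log2 change (x axis) over the measured members of 8 gene lists (y axis, number of genes in parentheses) in the 3 comparisons, from the fit with the deposit set as a block; error bars are the SE over genes, which are not replicates. Heat shock genes have a mean of 0.59 (median 0.37) in transfected and 0.08 in untransfected cells against control, while endoplasmic reticulum chaperones have 0.27 and 0.32. Within set 2 alone, which is not drawn, these means were 0.43 and 0.01 for heat shock and 0.115 and 0.24 for endoplasmic reticulum chaperones.

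Over 19775 genes, the log2 changes of transfected and of untransfected cells against the same controls correlated at r = 0.352 across genes, which are not independent replicates, with a covariance of 0.021. Unchanged groups simulated against shared controls gave a mean r of 0.406 and a covariance of 0.0233 with independent noise. That noise took its SD from the control arrays of both sets, so it takes in the set difference and does not show what shared controls alone give. When the sets' structure was kept, the mean r was 0.164 (range -0.57 to 0.76 over 100 draws) and the covariance 0.0062. The observed value lay inside that range. As no gene was called in untransfected cells, no overlap of genes was possible. Of the 4 probe sets called there, 3 were also among the 72 called in transfected cells, namely the 2 RAP1A probe sets and the unnamed one, while independent lists would share 0.00527, a value that leaves out the shared controls. Unchanged groups simulated against these controls shared 0, which says little, since none of 100 draws made a call for transfected cells. With no array in common, that is, with transfected against control cells in set 1 and untransfected against control cells in set 2, limma called 3277 and 3 probe sets higher, and the 2 RAP1A probe sets were in both, where independent lists would share 0.18.

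The lists of markers of other cell types were not called in transfected cells: leukocyte (mean -0.04), fibroblast (-0.02) and neuronal (0.08) markers had camera adjusted p of 0.317, 0.352 and 0.352. Of 13 neuronal markers, INA, an intermediate filament protein, rose with the set as a block (0.46, limma adjusted p = 0.0301, and 0.23 without the block), and adjusted over the list alone 3 rose with the block and 2 without it. Reference genes had a mean of 0.23 (adjusted p = 0.0656, and 0.000195 with the set as a block, where adjusted p = 0.533 with an estimated correlation). In untransfected cells with the block, fibroblast markers had a mean of -0.14 (adjusted p = 0.00305, and 0.36 with an estimated correlation), leukocyte markers -0.05 (adjusted p = 0.44), neuronal markers 0.00 with a downward test (adjusted p = 0.895) and reference genes 0.11 (adjusted p = 0.00828, and 0.588 with an estimated correlation), while within set 2 the means were -0.15 (adjusted p = 0.0311, and 0.528 with an estimated correlation), -0.03, -0.06 and, with an upward test, -0.004, the last 3 not called. Over both sets, the difference between 3-prime and 5-prime signal of ACTB was 0.89 in transfected and 1.21 in control cells (exact permutation p = 0.0303, two-sided; 0.364 after Benjamini-Hochberg over 12 tests), and that of GAPDH was 0.22 and 0.27 (exact permutation p = 0.491).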

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

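In this part, the tests of the RAP1A probe sets and of the spike-in controls, and for the zinc finger genes the use of an estimated correlation, of the genes not called and of exchanged arrays, were chosen only after the result was seen. Array 5 of the transfected cells stood apart from the other 5 on 4 measures, where its gap to the nearest array was larger than a test for outlying values allows. Its mean correlation with the arrays of its set was 0.970, against 0.990 to 0.991 for the others. DDB2 had a value of 9.44 there against 8.54 to 8.76, ACTA2 one of 9.04 against 8.02 to 8.34, and a probe set that carries several symbols one of 8.23 against 7.04 to 7.44. Of 68 groups of values tested 4 stood out, and chance gives about 3.4. As all 4 fell on this array and the groups share arrays, that count does not tell whether its deviation is chance.

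The RAP1A signal rose at 2 of 4 probe sets of that gene. A rise of the whole transcript is argued against, since the highest upper 95% bound of the other RAP1A probe sets was 0.63 on the log2 scale. Sequence that control cells lack, such as introduced DNA or its transcript, cannot be told apart from an induced transcript form: neither probe nor introduced sequences were analysed here, and the rank of the control means of both probe sets, at most at percentile 45.8 of all probe sets, decides nothing because levels of different probe sets are not comparable. A carry-over of transfected cells into the untransfected samples would pass on all rises in one proportion; in replicates 4 to 6 the untransfected arrays held 0.646% of the transfected rise of HSPA6 and a median of 21.2% over 165 rising genes, while the 9.68% and 9.19% at the 2 probe sets are not set against these, since transfected values of 13.92 to 14.56 there lie near those arrays' highest of 14.91 to 14.95, where a saturated signal would raise the share. The median decides nothing, because both rises are taken against the same controls: with unchanged untransfected cells simulated it ran from -26.7% to 84.3% and reached 21.2% in 27 of 100 draws. For the RAP1A probe sets, carry-over thus cannot be told apart from a response of the untransfected cells themselves. Nor can it be told apart from introduced sequence in cells classed as untransfected. The second probe set without a symbol rose by 1.23 in untransfected and 0.62 in transfected cells against control. Carry-over alone would give the reverse order, but limma did not call that difference (-0.61).

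The deposit sets differed at 20443 probe sets. The bacterial spike-in control probe sets were brighter in set 2 by 1.51 on the log2 scale (exact permutation p = 0.0002). That p is the smallest these 5005 splits can give. The probe set of 18S ribosomal RNA was brighter there too, by 5.48. A hybridization batch would fit the brighter spike-in values. A labelling batch stays open: the poly-A spike-in control probe sets averaged 3.29 in set 1 and 3.19 in set 2. Both means lie below the lowest array median of 5.05, so these dim values cannot tell whether labelling differed. A difference in the spread of values alone is argued against, since 13955 probe sets still differed after quantile normalization. No biological explanation was tested, as the labels name none.

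Among genes with ZNF symbols, a family noticed from the called genes and not a fixed list, 8 of 502 passed in transfected cells, among 32 of 19775 genes that rose, and with the set as a block 21 did, among them ZNF557 (0.96), ZNF256 (0.95) and ZNF416 (0.79). With the block camera's p for the family was 0.0317, and 0.147 with an estimated correlation, while over the 494 genes not called it was 0.091 with the block, 0.0241 without it, and 0.000169 with the block but without transfected array 5. A shift between the deposit sets does not enter the excess of their mean change over other genes, which is taken within each set. It was 0.052 in replicates 1 to 3 and 0.061 in replicates 4 to 6. The spread between arrays is not excluded as its source: over all 400 ways to exchange arrays within sets the excess had an exact permutation p = 0.36 (two-sided). The bound set in advance did not ask for that spread, and the camera p of 0.0317 takes in the called genes that drew attention to the family. Transfected array 5 is argued against as the source of the excess, which was 0.105 without it (camera p = 3.02e-05, and 0.0183 with an estimated correlation; exact permutation p = 0.015, two-sided, over 200 such exchanges of the within-set mean of 0.111), and so is brightness, as their median of 0.09 lay at percentile 100 of 10000 lists matched on mean value. A response to transfection may contribute and stays open.

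Other splits of the arrays test whether chance can be excluded. For transfected against control, 2 of 100 splits gave as many as 72 probe sets, the real one included; the other gave 4837 and put 5 of the 6 arrays of set 1 on one side, and splitting the 12 arrays by set gave 20757, which points to the set as a structure of the samples. Among splits that keep the sets balanced, with the set as a block, 1 of 100 reached 859, the real one, and the highest other gave 2. Of the 32 splits that part all 6 same-numbered pairs, the real one alone called any probe set (72, 859 with the set as a block and 1463 with the replicate number as a block, against 0 in the others). Chance is thus excluded for these counts, but not for the number of lists called, with 10 (36 of 100 splits, highest other 20), or 13 with the set as a block (12 of 100 splits within sets, highest other 17).

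Untransfected arrays lie in set 2, so the splits that compare like with like are the 20 that exchange arrays within set 2, too few for a share under 0.05. For untransfected against control, 2 of all 84 splits reached 4 probe sets, and the other, at 18636, took control arrays 1 to 3; within set 2 the real split gave 4 and the highest other 0, with or without the block. For transfected against untransfected 2 of 84 reached 8, and the other, at 566, set transfected arrays 1 to 3 apart; within set 2 the real split gave 8 and the highest other 0, and 25 against 1 with the block. The number of lists mostly followed the set: for untransfected against control 1 of 84 splits reached 22, but the 19 other splits within set 2 gave 13 to 20, and with the block the real 13 stood against a highest other of 14 (3 of 20 splits). For transfected against untransfected 6 of 84 splits reached 13 lists (highest other 15), and with the block the real 10 stood against 12 (3 of 20 splits).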

How the results depend on the processing

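The fits within a set with the replicate block, the list tests within a set, and those that combine the deposit set with quantile normalization, with an estimated correlation or with the omission of transfected array 5 were chosen after seeing the data. Where no cause is named below, the cause was not tested. For transfected versus control, 72 probe sets became 26 at an absolute log2 change of at least 1, 27 at an adjusted p under 0.01, 34 in a fit of the 2 groups only, 144 after quantile normalization, 44 with trend and robust, 111 with array weights, 37 with the brightest probe set per gene (fewer tests), 859 with the deposit set block, 2049 with it and without transfected array 5, 583 with it after quantile normalization, and 3770 and 4 within replicates 1 to 3 and 4 to 6, or 3588 and 6 there with the replicate block. With the replicate number as a block, a pairing that the numbers may or may not stand for, the count was 1463. Leaving out 1 array gave 34 to 91, with 34 without control 1, 43 without control 2, 44 without control 6, 38 without transfected 2 and 39 without transfected 6. For untransfected versus control, 4 became 2 after quantile normalization, 1 and 0 with the mean of all probe sets and the brightest probe set per gene in limma, which gave 955 and 944 of 19775 genes at an unadjusted p under 0.05, where chance gives 989, and 20559 against controls 1 to 3 only, which lie in the other set. Leaving out 1 array gave 2 to 4, with 2 without each of untransfected 1, 2 and 3. For transfected versus untransfected, 8 became 5 at an absolute log2 change of at least 1, at an adjusted p under 0.01 and in the 2 groups only, 13 after quantile normalization, 23 with array weights, 4 and 2 with 1 value per gene, 25 with the deposit set block, 49 with it and without transfected array 5, 14 with it after quantile normalization, 15311 against transfected 1 to 3 only and 3 against transfected 4 to 6 only. Leaving out 1 array gave 5 to 6, with 5 for each array but transfected 4. Untransfected arrays did not pair with arrays of the same number, which lie in set 1. Within set 2, with group means removed, untransfected 2 correlated best with control 5 (0.556) and transfected 5 (0.54), and untransfected 3 with control 6 (0.489) and transfected 6 (0.576, with 0.565 for transfected 4), while untransfected 1 had its highest values with control 4 (0.135) and transfected 5 (0.113); this is a hint from the data, not the design, and neither the comparisons with untransfected cells nor their splits take it into account. The replicate number as a block set untransfected arrays of set 2 beside arrays of set 1, with 18705 and 17553 calls for untransfected versus control and transfected versus untransfected.

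For the gene list tests, transfected versus control, 10 lists became 0 with an estimated correlation, 3 with fry, and 3 with the deposit set block and an estimated correlation, with or without transfected array 5. Within set 1 and set 2 alone 15 and 7 were called. Leaving out 1 array gave 5 to 13, with 6 without transfected 4 and 5 without transfected 6. In untransfected versus control, 22 lists became 0 with an estimated correlation, 0 with fry, 5 after quantile normalization, 13 with the deposit set block and 14 with it and without transfected array 5, 9 within set 2, and with the block and an estimated correlation 2, or 0 without that array; leaving out 1 array gave 18 to 22. In transfected versus untransfected, 13 lists became 0 with an estimated correlation, 0 with fry, 7 after quantile normalization, and 3 with the deposit set block and an estimated correlation, or 2 without transfected array 5, and 13 within set 2; leaving out 1 array gave 11 to 17. Directions of lists, given as the mean log2 change minus that of other genes, turned as follows where a call was involved. In untransfected versus control, DNA replication had -0.017 with the deposit set block, -0.028 with it and without transfected array 5, and -0.072 after quantile normalization; apoptosis regulators had -0.041 and -0.039 with the block, with and without that array, and oxidative phosphorylation -0.03 after quantile normalization. Within set 2 DNA replication had -0.07, apoptosis regulators -0.045, endocytosis and trafficking -0.001, hypoxia and glycolysis -0.056 and oxidative phosphorylation -0.047. In transfected versus untransfected, oxidative phosphorylation had 0.022 within set 2. With the deposit set block, oxidative phosphorylation had 0.096, reference genes 0.079 and NRF2 targets 0.139, and without transfected array 5 these had 0.068, 0.109 and 0.146, while nuclear import and export had 0.059 and RNA splicing 0.137. Camera's direction alone turned, with no change of sign, for endoplasmic reticulum chaperones there (-0.001, from -0.296) and for DNA replication with the replicate block (-0.265, from -0.01). These values were the same with an estimated correlation, which changes only the test. Other signs changed too. Within set 2 oxidative phosphorylation, RNA splicing and reference genes in transfected versus control had -0.025, -0.052 and -0.005, and NRF2 targets and DNA replication in transfected versus untransfected 0.122 and 0.191. After quantile normalization oxidative phosphorylation in transfected versus control had -0.045 (0.122 before), heat shock and chaperones in untransfected versus control -0.013 (0.232 before, a call that was lost), and NRF2 targets in transfected versus untransfected 0.024. With the replicate block the integrated stress response and p53 targets in transfected versus untransfected had -0.073 and -0.144 (0.145 and 0.114 before, none of them called). DNA replication there had -0.01, but 0.245 with the deposit set block, 0.279 with it and without transfected array 5, 0.198 after quantile normalization, 0.055 without dim genes and 0.001 to 0.037 without transfected 1, 2 or 3 or untransfected 2. The RAP1A representative had 4.67 in transfected versus control as the mean of all probe sets per gene, which takes in the 2 probe sets that rose. The shared response of 0.352 was 0.32 without dim genes, 0.563 over the 36 genes called in either comparison, 0.14 with transfected cells against controls 1 to 3 and untransfected against 4 to 6, and -0.681 with these controls exchanged. Over the alternatives fixed together with the lists, for single genes, 879 values kept their direction and side of the threshold, 153 no longer passed, 27 newly passed, 23 changed sign with no call in either fit and 1, the RAP1A representative above, changed direction with a call. Signal over background was not used here, so its limit on dim probe sets is unknown.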

Other observations

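With the set as a block, the largest falls in transfected cells beyond those of BTN3A2 and AMOT, by the naming rule applied to that fit after the values were seen, were NOG, which encodes the secreted BMP antagonist noggin (-0.86; limma adjusted p = 0.0122), IGFBP5, an insulin-like growth factor binding protein (-0.78; 0.0109), PHACTR3 (-0.76; 0.0174), PAQR5 (-0.70; 0.00406), the transcription factor gene EBF2 (-0.70; 0.0414) and SOWAHC (-0.66; 0.0353). SRPX, RIN2, PCDH18 and SOSTDC1, another secreted BMP antagonist, fell by 0.65, 0.64, 0.61 and 0.60. None of these genes passed without the block. In other lists the same fit raised RELB (0.62) and LIF (0.52) among 24 NF-kB and inflammatory genes, which were not called as a list (camera adjusted p = 0.205), the death receptor gene TNFRSF10B (0.54) among 26 apoptosis regulators (adjusted p = 0.599), and ACTA1 (0.52) beside ACTA2 among 21 actin and contractile genes (adjusted p = 0.136).

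A probe set that carries several symbols, singled out after its values were seen, was higher in transfected cells than in untransfected cells by 1.33 (limma adjusted p = 0.0339), a call lost in 8 of 9 fits that leave out 1 array (all but that without transfected 4) and in 4 of 11 other alternatives (adjusted p from 6.47e-06 to 1 over all of these), while untransfected and control cells had means of 6.76 and 6.75. A test of whether the effect of transfection differed between the sets found 0 probe sets with limma after adjustment and 3787 at an unadjusted p under 0.05, against 2731 that chance gives.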
